A study of Mus musculus with 6 samples.

How the data were processed

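Total RNA of whole bone marrow cells, taken after lysis of red cells, was extracted and 200 ng were labelled with biotin and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. There were 6 arrays, 1 per animal: 3 of Gfi1-KI and 3 of Gfi1-KD mice, all with the Nup98/HoxD13 transgene. Groups were taken from the genotype in the labels, and replicates were numbered in the order of the deposit, so the numbers pair no arrays. What the KI and KD alleles are is background knowledge and was not taken from the labels.

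The value table holds 1 intensity per probe set and array, summarised with MAS5 per the submitters' processing notes (no version is given), on a linear scale, as deposited. Each deposited array has a mean signal of 999.7 without its lowest and highest 2% of probe sets, so the authors' values are scaled to a common mean. The authors deposited a comparison table as well. Per the file headers it holds log2 RMA signals of the same arrays and a p-value of an analysis of variance of kd against wt. It also holds a step-up adjusted p-value, the ratio of kd to wt and a signed fold score (the ratio, or minus its inverse where the ratio is below 1), per the file headers. The software behind it is not given in the sources used here. Its group named wt was read as Gfi1-KI, the only other group. Values fill 1989 of its rows, each with an unadjusted p-value under 0.05, and 43112 rows are blank. From the RMA signals, the deposited ratio was recomputed within 0.1% and the deposited p-value within 1% for each filled row. This selection shapes everything that needs a gene name, because only these rows pair probe sets with genes. Among them, 1711 probe sets have 1 symbol (1512 genes), 56 have several, 219 have none and 3 are controls. A further 43326 probe sets of the value table are unnamed here. Symbols were updated through the Entrez identifier where the reference table for build 38 held it (1574 probe sets, 108 of them with a changed symbol). Coordinates were taken from that table, whose build number is that of the annotation in the deposited table.

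Signals under 1 were set to 1 (455 of 270606 values) and log2 was taken, with no further normalization. Non-control probe sets with a mean log2 signal at or above the median of all of them (6.95, a signal of 124) were tested, which left 22519. limma (version 3.58.1, in R 4.3.3) was run with lmFit and eBayes with a trend, two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. With 3 arrays against 3, an exact permutation test of 1 probe set cannot go below 0.1, so the p-values rest on limma's model. The procedure was tested on simulated data with the real means and spreads, 10 times with 200 changed probe sets each. The simulated noise was normal and independent between probe sets and arrays. Of the unchanged probe sets, 5.19% had an unadjusted p under 0.05, and 52 unchanged ones were called in all 10 simulations together. Folds of MAS5 signals are ratios of geometric means, and differences are Gfi1-KD minus Gfi1-KI, with the SE of limma. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

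The tests, the 28 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took Gfi1 and Gfi1b, and the 10 genes with the largest difference in each direction past the threshold. Where fewer passed, it filled up with genes at an unadjusted p under 0.01 whose groups do not overlap. It also took the 2 tested genes of each list with the highest level and the 2 with the smallest p, and the 3 genes with the largest fold in each direction of the deposited table. Cx3cr1, Ccr2, Ncapd2, Ncapd3, Smc4, Wee1, U2af1 and Sf3a1 are named beside the rule and were chosen after values were seen, as were the list members named without a value. Some members of the T and NK cell and interferon lists are not reported here. A gene is represented by its named probe set with the highest mean signal.

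Several planned steps had to differ. The count was made over probe sets and not over genes, since most probe sets are unnamed. Gene lists were tested with limma's camera (preset correlation 0.01, at least 2 genes, 10 lists) among the 792 named genes above the filter, which were themselves selected by p-value, so these tests compare directions among selected genes. fry, and camera over annotation terms, were not run for the same reason. Fisher's exact tests of direction (15 lists), of membership (28 lists) and of direction over 121 Gene Ontology terms with 10 to 500 named genes were chosen after seeing the data. So were the use of RMA signals and the reading of Gfi1-KI replicate 2 as a doubtful array. Alternatives tried for the count, the lists and each named gene were no level filter, a stricter one, quantile normalization, centring on the median, and added constants of 16 and 64. Others were the mean of a gene's probe sets, array weights, eBayes without a trend or robust, and each array left out in turn. An analysis of variance for the count and camera with an estimated correlation for the lists were run as well.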

Results

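Gene expression was measured in whole bone marrow of leukemic mice that carry the Nup98/HoxD13 transgene under Vav-1 control. The encoded fusion protein gives a myelodysplastic syndrome that can progress to acute myeloid leukemia. Gfi1, a transcriptional repressor that acts in granulocyte and monocyte development, differed between the groups. In 3 mice, labelled Gfi1-KI, the human GFI1 coding sequence stands at the mouse locus. The other 3, labelled Gfi1-KD, carry its version with reduced expression. Each animal gave 1 Affymetrix Mouse Genome 430 2.0 array, after lysis of red cells, and the labels state that the mice had the same age. The value table held signals of 45101 probe sets, 64 of them controls. Median signal per array ran from 117.0 to 148.1 (134.8 ± 16.1 in Gfi1-KD and 131.9 ± 2.92 in Gfi1-KI, SD, n = 3 each). The number of arrays limits the precision of every value.

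The 6 arrays did not group by genotype. The Gfi1-KI arrays correlated with each other at a mean Pearson r of 0.899 over probe sets, the Gfi1-KD arrays at 0.948, and arrays of different genotype at 0.917. Probe sets are not independent replicates. Gfi1-KI replicate 2 stood apart, with a median r of 0.889 against the other 5 arrays. There, 488 probe sets were 4-fold or more above the median of the other 5, against 43 to 182 on each other array, and 384 as far below, against 47 to 427. The transferrin receptor control probe set read 1615 on that array, 4.60 times the median of the other 5, and the pyruvate carboxylase control 5.54 times. Ratios of 3' to 5' control signal, a sign of RNA integrity, overlapped between the groups for 4 control genes. For Gapdh they were 0.801 to 0.830 in Gfi1-KD and 0.818 to 0.832 in Gfi1-KI, and for beta-actin 1.08 to 1.11 and 1.08 to 1.13. For the dimmer transferrin receptor they were 3.15 to 3.75 in Gfi1-KD and 2.23 to 3.19 in Gfi1-KI, where the 3.19 was on Gfi1-KI replicate 2. For pyruvate carboxylase the ratio was 3.01 on Gfi1-KI replicate 2 and 0.654 to 1.004 on the other 5 arrays.

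**Figure D1:**
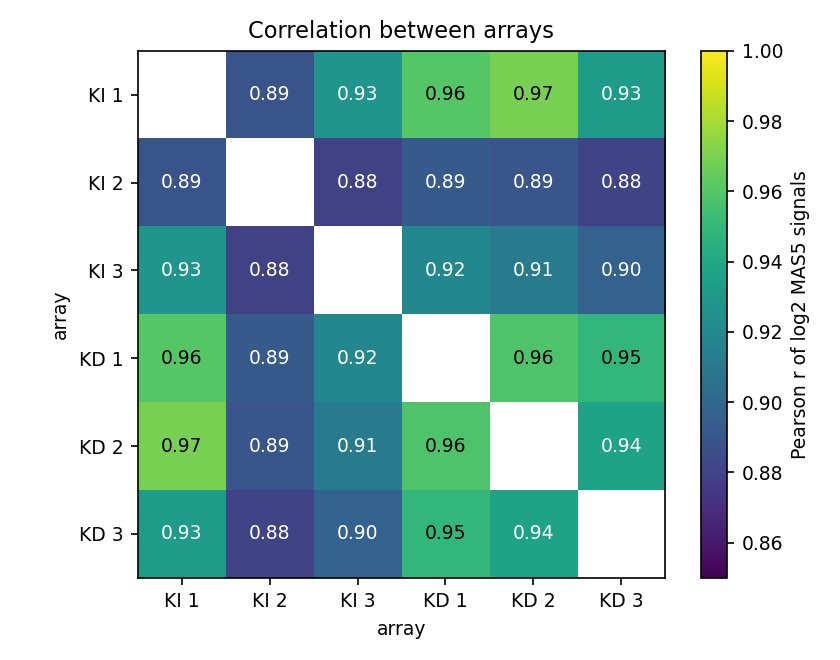
Pearson correlation of log2 MAS5 signals between each pair of the 6 arrays (rows and columns, KI and KD with replicate number; the color gives r and the diagonal is left blank). Gfi1-KI replicate 2 has r of 0.88 to 0.89 with each of the other 5 arrays, and the highest r, 0.97, joins Gfi1-KI replicate 1 and Gfi1-KD replicate 2.

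The comparison asks which transcripts of the leukemic marrow differ when Gfi1 is reduced. Ltf, Ceacam10, Itgb2l and Lrg1 had lower means in Gfi1-KD than in Gfi1-KI, and Ap1s3 and Cx3cr1 higher ones, but no probe set passed limma's test after correction for multiple testing. Ltf, which encodes the secondary granule protein lactoferrin (chromosome 9, 111019292 to 111042766, build 38), had a log2 signal of 9.21 ± 3.77 in Gfi1-KD and 14.14 ± 0.50 in Gfi1-KI (SD, n = 3 each), a 30.6-fold lower geometric mean. Its size rested in part on Gfi1-KD replicate 3: without that array the log2 difference was -2.76 instead of -4.93, and the RMA signals gave 18.7-fold with all arrays. Ceacam10 had a log2 difference of -4.68 ± 1.29 (SE), but its mean log2 signal in Gfi1-KD was 6.05, with 3.0 on replicate 3, below the level filter of 6.95. Without that array the difference was -3.16, and the RMA signals of its probe set were 11.8-fold lower. Itgb2l, a beta integrin relative, was 9.14-fold lower (-3.19 ± 0.66). Its log2 signal was 12.7 on Gfi1-KI replicate 3, against 10.9 and 11.0 on the other Gfi1-KI arrays. On Gfi1-KD replicate 3 it was 7.14, against 8.89 and 8.98 on the other Gfi1-KD arrays. The fold of Itgb2l thus rested in part on these arrays. Lrg1, a granule glycoprotein of neutrophils, was 7.90-fold lower (-2.98 ± 0.81). Its difference was -2.31 without Gfi1-KD replicate 3 and -3.65 without Gfi1-KI replicate 2. In each of these genes, all 3 Gfi1-KD arrays lay below all 3 Gfi1-KI arrays. For Ceacam10, Itgb2l and Lrg1 this was a condition of their selection. Ltf came from the authors' deposited table, selected by p on these arrays, so the separation is no added evidence. Among the higher means were Ap1s3, a subunit of the clathrin adaptor AP-1 (13.4-fold, 3.75 ± 0.38; 6.27-fold in the RMA signals), and Cx3cr1, the fractalkine receptor of monocytes (5.13-fold, 2.36 ± 0.73). Cx3cr1 had a log2 signal of 12.2 on Gfi1-KD replicate 3, against 10.2 and 9.97 on the other Gfi1-KD arrays, so its fold rested in part on that array.

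limma with Benjamini-Hochberg adjustment called 0 of 22519 tested probe sets at an adjusted p of 0.05 and 0 at 0.1. The smallest adjusted p was 0.314, for Ap1s3. At an unadjusted p under 0.05 there were 1217 probe sets, where chance alone gives 1126. Of these, 837 were higher and 380 lower in Gfi1-KD (68.8% higher). That share was 57.5% after each array was centred on its median. In 2554 probe sets (11.3%) the groups did not overlap, where chance gives 10%. A two-group analysis of variance on the same signals gave 1076 probe sets at an unadjusted p under 0.05 and 1 after adjustment, which has no gene name in the tables used here. Its log2 means were 8.79 and 9.11 in Gfi1-KI and Gfi1-KD, and its SDs 0.0065 and 0.0042. limma, which shares variance between probe sets, gave it an adjusted p of 0.865. In simulations of this design, limma recovered 11.0% of probe sets changed by 1 on the log2 scale, 50.1% of those changed by 2 and 88.5% of those changed by 4.

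**Figure D2:**
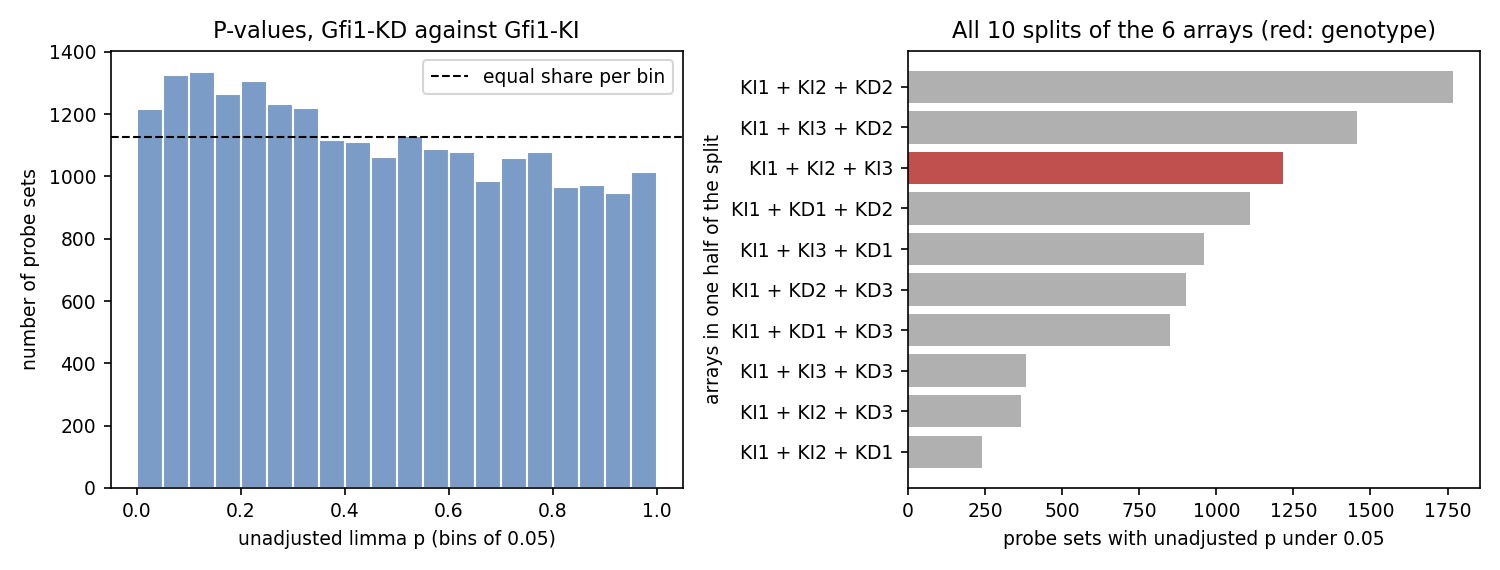
Left, histogram of unadjusted limma p-values of the 22519 tested probe sets in bins of 0.05 (number of probe sets; the dashed line is the equal share per bin, 1126). Right, number of probe sets at an unadjusted p under 0.05 for each of the 10 ways to divide the 6 arrays into 3 and 3, named by the arrays of the part that holds Gfi1-KI replicate 1; the genotype split, in red, gave 1217 and the highest other split 1766.

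Among genes with an unadjusted limma p under 0.01 and no overlap between the groups, the higher MAS5 means after Ap1s3 were of Rab17, a small GTPase of membrane traffic, and Eps8, an actin regulator (5.49-fold, log2 difference 2.46 ± 0.64, SE). Others were Pid1 (5.12-fold), Cryzl2 (5.11-fold), 2900026A02Rik, and Itgb5, an integrin subunit (4.53-fold). The chemokine gene Ccl3 (4.48-fold), Pam, a peptide-amidating enzyme (4.25-fold), and Ptpro, a receptor tyrosine phosphatase (3.84-fold), completed the 10. Eps8 had a log2 signal of 7.43 on Gfi1-KI replicate 3, against 9.75 and 9.19 on the other Gfi1-KI arrays, so its fold rested in part on that array. Lower means in this selection, beside those of Ceacam10, Itgb2l and Lrg1, were of AA467197, Ankrd22 and the transcription factor gene Klf5 (5.30-fold). Actn1, an actin cross-linker (4.62-fold), the prion protein gene Prnp (4.34-fold), Rasl11b (3.66-fold) and Tbrg1 (3.43-fold) were lower too. The fold of Actn1 rested in part on Gfi1-KI replicate 3, with a log2 signal of 12.7 against 10.6 and 10.9 on the other Gfi1-KI arrays. In Rab17 and 2900026A02Rik the Gfi1-KI means (log2 6.40 and 6.27), and in AA467197 and Ankrd22 the Gfi1-KD means (6.02 and 5.74), lay below the level filter of 6.95, so no MAS5 fold is given. In the RMA signals of the authors' deposited table, Rab17 was 4.82-fold and 2900026A02Rik 2.86-fold higher, AA467197 was 7.77-fold and Ankrd22 4.11-fold lower, and Pam was 2.75-fold higher. For genes with several listed probe sets, the RMA folds could differ between them. Prnp was 4.75-fold lower in the probe set used here and 1.48-fold in the other. Pid1 was 5.05-fold and 1.83-fold higher, Rab17 4.82-fold and 1.75-fold, and Eps8 6.25-fold against 6.56-fold and 3.24-fold, in that order. Those of Ceacam10 were close, 11.8-fold and 12.7-fold lower. The size of the MAS5 difference of AA467197 also depended on which array was left out. All 3 Gfi1-KD arrays lay beyond all 3 Gfi1-KI arrays for each gene of this selection, which is how they were selected. None passed the test, with a limma adjusted p of 0.865 for each but Ap1s3. In all, 87 higher and 24 lower genes met this selection, of which 10 each are named. They came from the 792 genes above the level filter that the authors' deposited table names, without immunoglobulin and T cell receptor segments. Those genes were themselves selected by p on these arrays, so the 2 counts do not describe all probe sets.

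**Figure D3:**
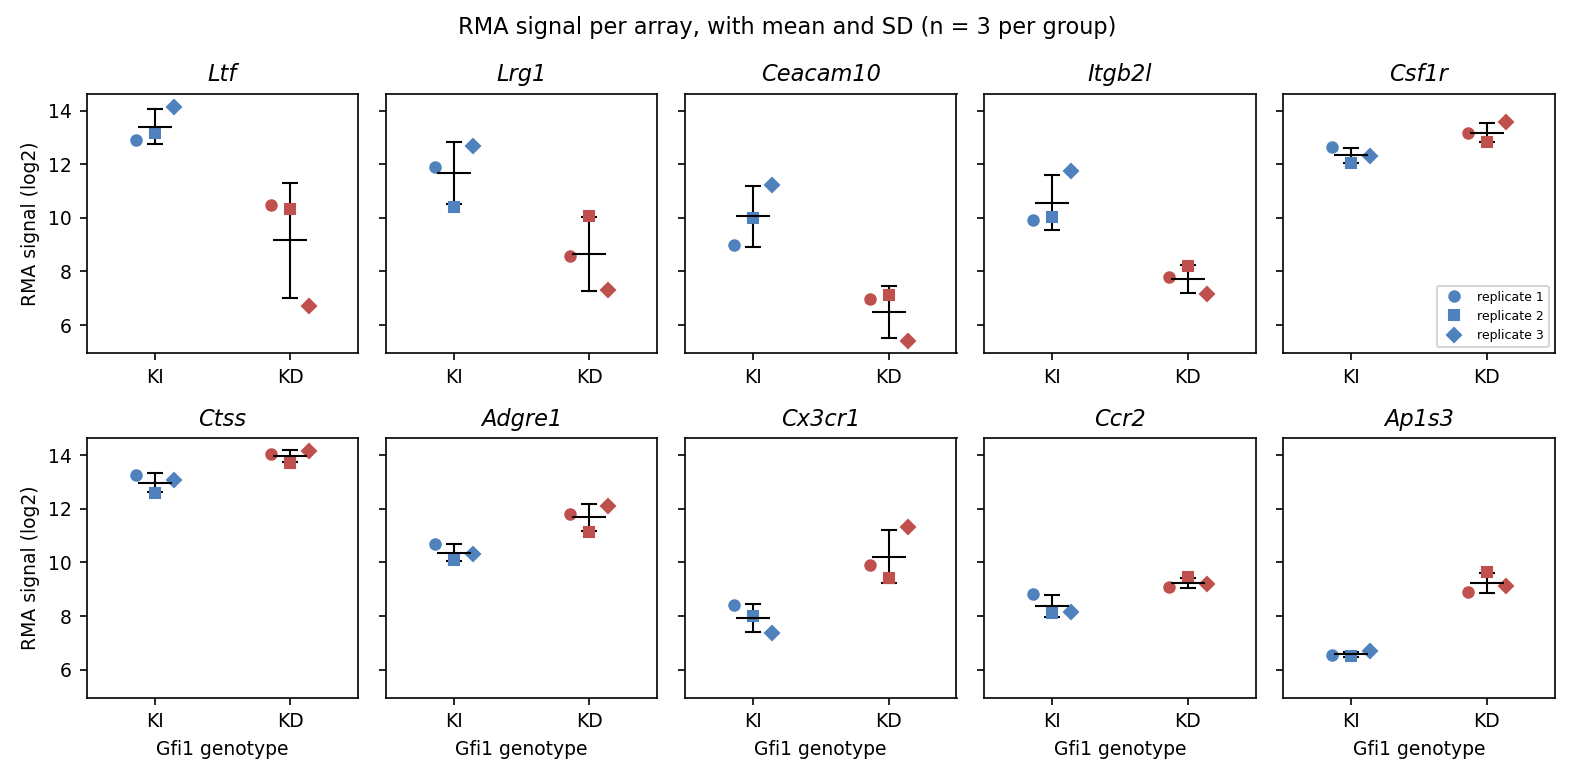
RMA signal (log2) on each array for 10 genes, Gfi1-KI in blue and Gfi1-KD in red; symbols mark the replicates, the long tick is the mean and the error bar the SD (n = 3 per group). Ltf, Lrg1, Ceacam10 and Itgb2l lie lower on all Gfi1-KD arrays and the other 6 genes higher, and Ltf is lowest on Gfi1-KD replicate 3.

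Gene lists fixed before the data were examined could be followed only through the genes that the authors' deposited table names. That table was selected on these same arrays, so a list's count is not independent evidence of its direction. Directions of list genes given without a fold are those of the RMA signals, and folds are of the MAS5 signals. The monocyte and macrophage list had 6 of its 32 genes named (18.8%, against 6.06% of the genes of the other lists), and all 6 were higher in Gfi1-KD. They were Csf1r, the receptor of a monocyte growth factor (1.78-fold, log2 difference 0.84 ± 0.20), the lysosomal protease gene Ctss (1.90-fold, 0.92 ± 0.19) and Adgre1, a macrophage surface receptor (2.42-fold, 1.28 ± 0.30). The others were Cx3cr1, the chemokine receptor gene Ccr2 (1.97-fold) and Hmox1, heme oxygenase (1.63-fold). Set against the other named genes with limma's camera, this list had an adjusted p of 0.0592 over 10 lists, and adjusted p = 0.553 with an estimated correlation. The late neutrophil list had 2 of 35 genes named (5.71%, against 6.61% of the genes of the other lists), Ltf and Lrg1. Both were lower (camera adjusted p = 0.0883, and adjusted p = 0.553 with an estimated correlation). Without Gfi1-KI replicate 2 both lists had a camera adjusted p of 0.0536. All 8 genes had the same direction without that array, but so did every listed probe set in the RMA signals. The kept direction thus sets neither list apart. No member of any list passed limma's adjustment over all probe sets tested. Adjusted over the list alone, 6 monocyte and 2 late neutrophil genes passed; these had entered the table by their p on the same arrays, so such a count is no evidence for any list here. Membership of the table did not set the monocyte list apart from the other lists once 28 lists were tested (Fisher's exact test, two-sided, p = 0.0145, adjusted 0.406), nor did direction over 15 lists (p = 0.0403, adjusted 0.594).

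The G2/M cell cycle list had 3 of 38 genes named, each by 1 listed probe set, and unlisted ones cannot be named here. These genes each had a lower mean in Gfi1-KD: Cenpa, the centromeric histone (2.37-fold lower), Cenpf (1.30-fold) and Top2a, topoisomerase II (1.25-fold). Their camera adjusted p was 0.0883, adjusted p = 0.553 with an estimated correlation, and from 0.0536 (without Gfi1-KI replicate 2) to 0.195 (without Gfi1-KI replicate 1) with 1 array left out, with 0.134 without Gfi1-KD replicate 3. Of the reported Gfi1-repressed targets, 2 of 27 were named and both were higher, Csf1r and the transcription factor gene E2f6 (1.28-fold; camera adjusted p = 0.314). Dendritic and MHC class II genes had 3 of 20 named, all higher, H2-DMa (1.97-fold), H2-DMb2 (1.55-fold) and Tcf4 (1.68-fold), with a camera adjusted p of 0.287. For NF-kB and inflammatory cytokines, 3 of 30 were named, with Ccl3 and Icam1 (2.08-fold) higher, Ptgs2 lower and a camera adjusted p of 0.190. The lists of p53 targets (3 of 33, 2 higher), histone acetylation and the LSD1 complex (5 of 42, 3 higher), acute myeloid leukemia signalling and transcription factors (4 of 42, 2 higher) and ribosomal proteins (2 of 49, both higher) each had a camera adjusted p of 0.832. For the p53 and histone lists the camera direction was lower while the median RMA difference of the named members was higher (log2 0.17 and 0.26). Adjusted over the list alone, a count that is no evidence for the reason given, 1 gene passed in the G2/M list, 1 in the Gfi1 target list, 1 in the dendritic list, 2 in the NF-kB list and 0 in the other 4.

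Other lists had too few named genes above the level filter for a set test; with 1 such gene, adjustment over the list alone leaves its p as it was. Higher in Gfi1-KD were Hoxc6 of the HOX and MEIS list (1 of 29; 1.80-fold), Mgst1 of the primary granule list (1 of 16), Fcrla, Foxo1 and Pax5 of the B cell list (3 of 31), Prdm1 of the plasma cell list (1 of 11), Cd28 of the T and NK cell list (2.96-fold), and Tespa1 of the stem and progenitor list (1 of 33; 2.14-fold). So were Ccnd1 of the G1/S list (1 of 37; 1.71-fold), Bcl2l1 and Bcl2l11 of the BCL2 family (2 of 19), Ier5 of the immediate early list (1 of 28) and Hmox1 of the heme and iron list (1 of 22). Lower were Epb41 of the erythroid list (1 of 40; 1.51-fold) and Aldoa of the glycolysis list (1 of 19; 1.38-fold). The mast cell, basophil and eosinophil list (2 of 27) and the stroma and endothelium list (2 of 30; Pecam1 2.0-fold higher) each had 1 gene in either direction. The megakaryocyte list (0 of 22), oxidative phosphorylation (0 of 48) and the sex-linked list (0 of 5) had no named gene, which leaves their levels open. Gfi1 and Gfi1b themselves were named by no row, so the level of Gfi1 was not analysed here.

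The authors' deposited table lists 1135 probe sets with a higher and 854 with a lower RMA signal in Gfi1-KD at an unadjusted p under 0.05, which is 4.41% of 45101 where chance gives 2255; 3 of them are control probe sets. The largest folds above 1 there were of Arntl2 (16.6-fold), Eps8 (6.56-fold) and Ap1s3 (6.27-fold), and the largest below of Ltf, Ceacam10 and Lrg1 (-18.7, -12.7 and -8.08 as signed folds). The Arntl2 value belongs to the dimmer of its probe sets. The brighter one is listed at 1.34-fold in the authors' deposited table and had a log2 difference of 1.88 ± 0.43 (SE) in the MAS5 signals, with a Gfi1-KI mean of 6.91, below the level filter. Of 162 genes with several listed probe sets, 158 had all of them in 1 direction. Probe sets at a p of 0.05 or more are absent there, so a gene's unlisted probe sets could not be compared. The smallest step-up p of the authors' deposited table was 0.211, and 0 probe sets had one under 0.05. Of the listed probe sets above the level filter, 1007 of 1034 (97.4%) had the same direction in the MAS5 signals, and 440 had an unadjusted limma p under 0.05. Below the filter 756 of 952 (79.4%) had the same direction. Without Gfi1-KI replicate 2 all listed probe sets had the same direction in the RMA signals, and 903 (45.4%) had a p under 0.05.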

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

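The tests of a single array, of the summarization and of RNA quality, and the choice of the neutrophil and monocyte pattern out of 28 lists, were made after the values had been seen.

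Some control probe sets, which were left out of limma's tests, separated the groups. Of 60 bright controls, 10 had all 3 Gfi1-KD arrays above all 3 Gfi1-KI arrays and 5 had all below, where chance gives 5% in each direction; probe sets of 1 transcript are not independent. For the 3', middle and 5' probe sets of Gapdh the ratios of mean signal, Gfi1-KD over Gfi1-KI, were 1.04, 1.05 and 1.05. For bacterial control transcripts they were 1.13 (DapX-5_at), 1.10 (DapX-M_at), 1.10 (r2-Bs-dap-M_at), 1.28 (r2-Bs-lys-5_at), 1.41 (r2-Bs-thr-5_s_at), 1.45 (r2-Bs-thr-M_s_at) and 1.26 (ThrX-M_at). These ratios are of the 10 higher controls only, and values of the 5 lower ones are not given here.

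The first pattern is the number of probe sets at an unadjusted p under 0.05, 1217 between the genotypes. Among the 10 ways to divide the 6 arrays into 3 and 3, 3 gave as many, the genotype split included, and the highest other split gave 1766. The count thus lay within the range of the other splits, which was the prediction made beforehand for a count made by chance. With 10 splits the share cannot be under 0.1, and the splits cannot exclude an effect of genotype on some of the probe sets.

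The second pattern is the lower late neutrophil genes (Ltf and Lrg1) beside 6 higher monocyte genes in Gfi1-KD, a hypothesis that reduced Gfi1 may go with a shift between these lineages. A single array as its source stays open: the median log2 difference of the 8 genes, each taken in its direction, was 1.13 and at least 83.2% of that without any 1 array, but these genes were selected on all 6 arrays, and the mean of Ltf and Lrg1 went from -3.96 to -2.54 without Gfi1-KD replicate 3. On the summarization, the MAS5 median was 98.1% of the RMA one and all 8 genes had the same direction in both. These genes were listed by RMA p and lay above the level filter, where 97.4% of listed probe sets had 1 direction in both. The comparison was thus nearly fixed beforehand and cannot decide. Whether marrow of Gfi1-KD mice held fewer neutrophils for monocytes cannot be told apart from a change within cells. Only 2 of the 35 late neutrophil and 6 of the 32 monocyte list genes were named, and the rest of both lists could not be followed. The means of the 2 groups of genes had a Spearman rho of -0.829 over the 6 arrays (exact permutation p = 0.0583) and a Pearson r of -0.888 (exact permutation p = 0.00972), with r of -0.762 over the 4 arrays left without Gfi1-KI replicate 3 and Gfi1-KD replicate 3, the farthest from the median. The genes had been selected for opposite group differences, and within genotypes r was 0.0063 in Gfi1-KI and -0.965 in Gfi1-KD, over too few arrays to test.

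The third pattern is the set of genes in the authors' deposited table. DNA of another mouse strain carried beside the targeted Gfi1 locus might put them near it, had this DNA differed between the groups. Both groups carry a targeted allele there, and whether it differed is not known here. Of 1308 protein-coding table genes, 16 (1.22%) lay within 10 Mb of Gfi1 (chromosome 5, 107716655 to 107725805, build 38), against 224 of 21896 protein-coding genes (1.02%). Among the 16 was 2900026A02Rik, named above for its higher mean. The odds ratio was 1.21 (95% interval 0.679 to 2.03, Fisher's exact test, p = 0.476), which leaves this open. A difference in RNA integrity stays open too. The 3' to 5' ratios of 4 control genes overlapped between the groups, but without Gfi1-KI replicate 2 only those of 3 did, with the transferrin receptor ratios higher on each Gfi1-KD array than on the other Gfi1-KI arrays. The genotype stays open, untested by any of these.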

How the results depend on the processing

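The annotation term test, the RMA signals for lists and genes, and the reading of Gfi1-KI replicate 2 as a doubtful array were chosen after seeing the data. No paired analysis was possible because the labels give the groups no shared replicate numbers. Gfi1 itself, the count over genes, fry and camera over annotation terms were planned and not run. The count of probe sets past an adjusted p of 0.05 was 0 under each alternative with limma, and 1 with the analysis of variance. The 1217 probe sets at an unadjusted p of 0.05 became 2311 with no level filter and 690 with the stricter filter, as more or fewer were tested. Leaving out 1 array gave 539 (without Gfi1-KD replicate 3) to 2126 (without Gfi1-KI replicate 1), with 655 without Gfi1-KD replicate 1 and 1396 without Gfi1-KI replicate 2. The monocyte list (camera adjusted p 0.0592) passed with no level filter (0.00633) and with arrays centred on their median (0.0418), and ranged from 0.0212 (without Gfi1-KD replicate 3) to 0.0730 with 1 array left out. It also passed without Gfi1-KI replicate 1 (0.0348), Gfi1-KD replicate 1 (0.0492) or Gfi1-KD replicate 2 (0.0411). With an estimated correlation, its adjusted p was 0.553. The late neutrophil list (0.0883) ranged from 0.0110 (without Gfi1-KD replicate 3) to 0.176 and also passed without Gfi1-KD replicate 2 (0.0455). Its adjusted p was 0.553 with an estimated correlation, too. With RMA signals these lists had 0.180 and 0.215. The cause was not tested. No other list passed under any alternative. The stricter filter left 4 lists with too few genes for a test (G2/M, dendritic, NF-kB and p53). Annotation terms past 0.05 numbered 2 with RMA directions and 1 with MAS5 directions. Of 1024 values of named genes under alternatives, 962 had an adjusted p, of which 0 passed, and the RMA values were not tested; 7 turned direction, in 2 genes: Rps28 (0.04) was -0.0061 with arrays centred on their median, and Sf3a1 (0.01) was -0.0437 with quantile normalization, -0.0421 with centring, -0.0316 to 0.0709 with 1 array left out (below 0 also without Gfi1-KI replicate 1, -0.0152, and Gfi1-KD replicate 3, -0.0071) and -0.163 in RMA signals. Adjusted p-values of named genes were 0.144 or more under the alternatives.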

Other observations

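The test of annotation terms was chosen after seeing the data, and it counts genes as independent, which co-regulated genes are not.

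Genes of mitosis and of RNA splicing in the authors' deposited table were mostly lower in Gfi1-KD. Of 16 table genes annotated to mitotic nuclear division, 14 were lower. Among them were the condensin genes Ncapd2 (1.49-fold lower in the MAS5 signals), Ncapd3 (1.18-fold) and Smc4 (1.27-fold). The kinase gene Wee1 (1.27-fold), the cohesin regulators Sgo1 and Wapl, and Clasp1 and Haus2 of the spindle were lower too. Phf13 and Vrk1 were higher. Against 484 lower genes among 1109 annotated ones, the 14 of 16 gave an adjusted p of 0.0271 over 121 terms (Fisher's exact test, two-sided), and 0.0492 with the directions of the MAS5 signals. RNA splicing had 14 of 16 lower as well, including Hnrnpa3, Hnrnpm, Srsf10, Zrsr2 and U2af1 (1.30-fold lower in the MAS5 signals), with Slu7 and Tra2b higher (adjusted p = 0.0271). That call was lost with the MAS5 directions (adjusted p = 0.174), where 4 were higher and Sf3a1 was level (1.01-fold). The genes were selected on the same arrays, and none passed limma's adjustment over all probe sets.

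Terms that did not pass included cell cycle, with 30 of 45 genes lower (adjusted p = 0.0766), and cytokine-mediated signaling, with 15 of 17 higher (adjusted p = 0.157), among them Csf1r, Ccr2, Cx3cr1, Il10ra, Ifnar1 and Irak4.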
